A study of Mus musculus with 9 samples.

How the data were processed

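Chromatin accessibility was measured by ATAC-seq in 9 libraries of 3 mouse E14 embryonic stem cell lines, 3 libraries each of WT, TetR and TetR-MYBTA, grouped by their titles. Cells were lysed and DNA was tagged with Nextera Tn5 transposase, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore 0.6.10, Bowtie2, Picard, deepTools 3.5.5 and HOMER 4.11, and the mm10 build. Whether reads were shifted for the Tn5 insertion offset, and whether blacklisted regions were removed, is not given in the sources used here.

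The deposited data are 1 list of peaks per library. Peaks were called by HOMER in each library separately, with no pooling and no control library, per the file headers. The headers give a false discovery rate of 0.001, a 4-fold excess over the surrounding 10 kb, a local Poisson p-value of 0.0001, at most 1 tag per position, and a threshold of 11 or 12 tags per peak. The score in column 5 of the deposited lists is 1 in every row, so it carries no ranking, and each list has 1 peak width apart from 1 peak. Starts and ends are positions in base pairs as the authors deposited them, written here counting from 1. Tag counts per peak were not used here, so peaks were compared as present or absent.

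The plan ranked peaks by score, or by width where the score was constant. Both were constant, so the row order of each list was used instead. Row order followed the peak numbers that HOMER assigns within each chromosome, with a lowest rank correlation of 0.9898, in TetR-MYBTA replicate 3. A region's percentile is its place in the list, 100 being the first row. Shorter lists reach less far down, which is why lists of equal length, the first 45136 rows of each, were also tried.

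Total tags and tags in peaks were taken from the headers. They ranged from 16.4 M to 23.0 M tags and from 5.48 to 9.78% of total tags, and no interval is given for single peaks because their counts were not used. Peaks overlapping by at least 1 bp in any library formed 1 union region. Genes came from the RefSeq table for GRCm38.p6, whose coordinates are those of mm10, with 21883 protein-coding genes. That table gives no strand, exons or introns, so positions within 1 kb of either gene end, inside a gene and between genes replaced promoters, exons and introns. The planned motif and tet operator search needs genome sequence and was not run. Of 198 listed gene symbols 196 were used, since 1 was unmatched and 1 was a second name of another listed gene.

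Groups were compared by two-sided exact permutation tests of the difference of means, with Benjamini-Hochberg adjustment over lists, chromosomes or library measures. Shares were also taken in 2-Mb windows with at least 90 peaks over all libraries. Chromosomes 1 and 11 were divided where 2 stretches fitted the log ratios best by least squares, and stretches of X and 6 were runs of at least 3 windows with a ratio of at least 1.3, rules set after the data were seen. Counts of private regions were ranked among all 84 choices of 3 libraries, and counts between pairs of lines among 10 splits. The gene lists, main tests and most alternative settings were set before the data were examined; the chromosome shares of TetR against the other 6 libraries, and 10000 random draws of as many regions on each chromosome as a line had private ones, were added afterwards. Regions with a peak in all 9 libraries were also ranked among themselves in each list, so that every list ranked the same regions. Named regions were the 8 with the highest mean percentile in each direction for TetR-MYBTA against the other 6 libraries and against TetR, and the 4 highest for TetR against WT, each named by the nearest protein-coding gene; some of these regions are not reported here. Named genes were also those of a fixed list with a peak at a gene end in all libraries on one side and none on the other, and Myb, Pou5f1, Nanog, Sox2, Klf4 and Esrrb in every case. In simulated presence data of 116362 regions, 200 of 200 regions planted as private to TetR-MYBTA were recovered. They met the counting rule by construction, so this checks the counting only and says nothing of sensitivity near the calling threshold. Separately, the exact test was run on random normal values, 3 against 6, with no effect. It gave an unadjusted p-value under 0.05 in 4.9% of those runs.

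Alternatives were lists of equal length, the upper 50% of each list, a stricter overlap rule, merging of peaks up to 200 bp apart, autosomes only, presence in at least 2 of 3 libraries, absence of any peak within 1 kb, leaving out each library, the replicate number as a block, distances of 2.5 kb for gene ends and 10 kb for gene lists, and 200-kb windows. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.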

Results

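Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 3 lines of E14 mouse embryonic stem cells of a variant named TOT2N. One line was unmodified (WT), one carried a stably integrated TetR construct, and one carried a TetR-MYBTA construct. TetR is the DNA-binding tetracycline repressor, and the series title places the work in the study of MYB activity, enhancer activation and enhancer-promoter contacts. MYB is a transcription factor of blood progenitors. Each line had 3 libraries, 9 in all, and the labels do not state whether these came from separate cultures, so the p-values measure the spread between libraries, which may be technical. Total tags ranged from 16.4 M to 23.0 M per library, and the lists held 45136 to 70230 peaks.

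The first comparison asked how much open chromatin each line showed. The TetR-MYBTA libraries had 53909 ± 7722 peaks (SD, n = 3), the TetR libraries 64983 ± 5796 (SD, n = 3) and the WT libraries 59762 ± 3247 (SD, n = 3). Peaks covered 10.8 ± 1.60 Mb in TetR-MYBTA, 12.7 ± 1.04 Mb in TetR and 12.1 ± 0.617 Mb in WT, and median peak width was 201 ± 7.64 bp, 196 ± 1.73 bp and 203 ± 2.00 bp. Each list has 1 peak width apart from 1 peak. Covered length therefore follows from peak number and that width, and is not a separate measure of open chromatin. Neither peak number (two-sided exact permutation p = 0.119) nor covered length (exact p = 0.0595) separated TetR-MYBTA from the other 6 libraries. Tags in peaks made up 6.83 ± 1.17% of total tags in TetR-MYBTA, 9.60 ± 0.260% in TetR and 7.90 ± 0.160% in WT (SD, n = 3 each). All 3 TetR-MYBTA libraries lay below the other 6 (exact p = 0.0238), but the difference did not pass after adjustment over 8 library measures (adjusted p = 0.0635), and the unadjusted call ended without TetR-MYBTA replicate 3 (exact p = 0.143) or TetR replicate 3 (exact p = 0.0714). A comparison of 3 against 3 libraries cannot give a p below 0.10, and one of 3 against 6 cannot go below 0.0119.

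**Figure D1:**
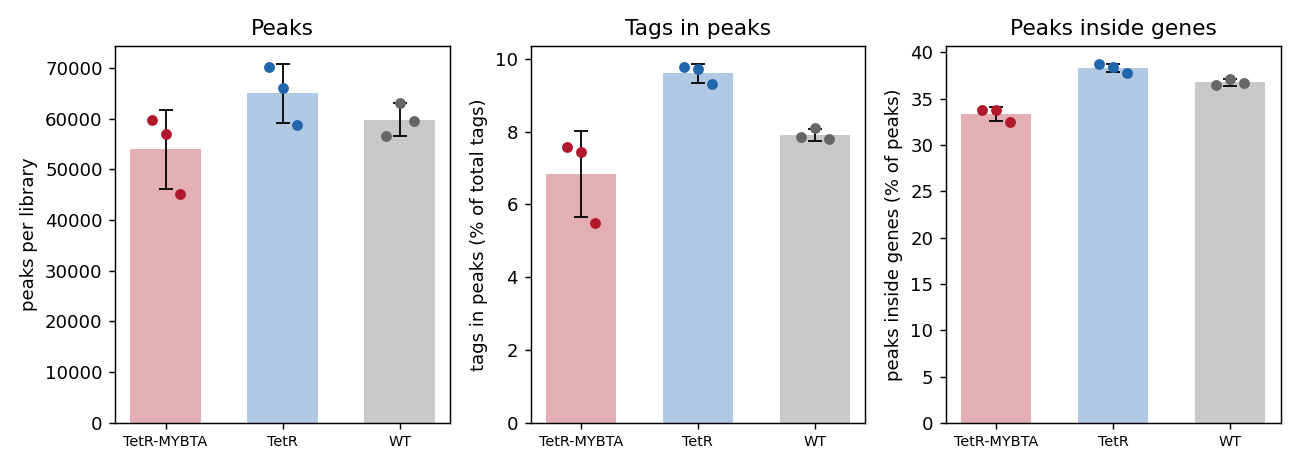
Peaks per library, tags in peaks as a percentage of total tags, and peaks inside protein-coding genes as a percentage of peaks, by line. Points are libraries, bars means and error bars SD (n = 3); the TetR-MYBTA libraries averaged 33.3% of peaks inside genes, against 38.3% in TetR and 36.8% in WT.

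Libraries of one line resembled each other more than libraries of different lines. The Jaccard index, the length shared by 2 peak sets divided by their joint length, averaged 0.466 within lines and 0.409 between lines, and of the 280 ways to form 3 groups of 3, only the real one gave so large a difference (exact p = 0.00357). TetR-MYBTA was the line furthest from the others, with a mean index of 0.391 with TetR and 0.404 with WT, against 0.432 between TetR and WT. Within lines the index averaged 0.441 in TetR-MYBTA, 0.485 in TetR and 0.473 in WT. Among the TetR-MYBTA libraries, replicate 3, the shortest list, had the lowest index with every TetR and WT library (0.363 to 0.394). The ranking of TetR-MYBTA as furthest thus does not separate distance between lines from lower agreement within TetR-MYBTA.

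Peaks of TetR-MYBTA lay less often inside genes. Inside protein-coding genes were 33.3 ± 0.763% of TetR-MYBTA peaks, against 38.3 ± 0.459% in TetR and 36.8 ± 0.360% in WT (SD, n = 3 each). Between genes were 45.6 ± 1.29%, 41.6 ± 0.746% and 42.3 ± 0.512%. Both shares separated TetR-MYBTA from the other 6 libraries (exact p = 0.0119 each, adjusted p = 0.0476). Peaks within 1 kb of a gene end made up 21.0 ± 2.05% in TetR-MYBTA and 20.5 ± 1.04% in the other 6 (exact p = 0.595). With lists of equal length this share was instead lower in TetR-MYBTA, by a difference of -2.04 percentage points (exact p = 0.0119).

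The regions opened or lost in TetR-MYBTA were counted over 116362 union regions, of which 26020 had a peak in all 9 libraries. A peak in all 3 TetR-MYBTA libraries and none of the other 6 was found in 683 regions, and the reverse in 1349. TetR had 1557 such private regions and lacked 297, and WT had 665 and lacked 176. The excess of missing over private regions in TetR-MYBTA turned around with lists of equal length, where private regions outnumbered missing ones in every line, to 1294 private and 687 missing, and without TetR-MYBTA replicate 3, the shortest list, to 1859 private and 1625 missing. Of the private TetR-MYBTA regions 3.51% lay within 1 kb of a gene end and 69.3% between genes, against 15.7% and 45.5% of all regions (Fisher's exact p = 1.94e-24 for gene ends, across regions, which are not independent replicates). Other regions seen in few libraries also lay near gene ends less often than all regions did: the share was 6.74% in regions private to TetR, 7.37% in those private to WT and 9.59% in those of 1 library, against 29.7% of those in all 9. Between genes lay 40.3% of regions private to TetR and 48.9% of those private to WT. Regions missing only in TetR, with a peak in all TetR-MYBTA and WT libraries, lay between genes in 67.7% and near gene ends in 6.06%. A high share between genes was thus not particular to regions private to TetR-MYBTA. Of the regions private to TetR-MYBTA, chromosome 1 held 182 (26.6%) and chromosome 11 held 88 (12.9%), while 8.66% and 6.15% of all regions lay there.

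The leading private regions of TetR-MYBTA, by place in the peak lists, were mostly away from gene ends (mm10 coordinates throughout). The first lay at chromosome 8, 128602708 to 128602937, 82.8 kb from Itgb1, which encodes integrin beta 1. Others lay inside Il9r, the interleukin 9 receptor gene (chromosome 11, 32196169 to 32196430), inside Tmem178 (chromosome 17, 80948822 to 80949030 and 80949470 to 80949710), 15.7 kb from the nuclear pore gene Nup160 (chromosome 2, 90661460 to 90661668) and 3.22 kb from Rc3h1, which encodes an RNA-binding ubiquitin ligase (chromosome 1, 160903087 to 160903295). A second region near Rc3h1 (chromosome 1, 160880728 to 160881144) had a peak of another line within 1 kb. Among the leading regions missing in TetR-MYBTA, those near Zfp180, Frmd8, Klf12, Tet2, Adrb3 and Iffo1 had a TetR-MYBTA peak within 1 kb. One without such a peak lay inside Uck2, a uridine-cytidine kinase gene (chromosome 1, 167279289 to 167279567). Over all such regions, 619 of the 683 private and 1212 of the 1349 missing ones had no peak of the absent libraries within 1 kb. Naming by that rule was added after the data were seen: the leading missing regions were then near Uck2, Ptms, Nectin3, Cop1, Ptprn2, Opa1, Ldlrad4 and Klhl42, and Bhlhe40 and Ddx58 joined the private ones.

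TetR-MYBTA was next compared with TetR, the construct without the MYB part. In 1627 regions all 3 TetR-MYBTA libraries had a peak and no TetR library did, and 5157 regions showed the reverse. With lists of equal length, which by itself draws such counts together, they were 2834 and 2838. The TetR excess kept its direction without TetR-MYBTA replicate 3 (3690 and 5839). It also did in the upper 50% of each list (1196 and 3101), but that setting keeps the relative lengths of the lists. Leading regions of TetR-MYBTA were near Triqk, Pou2f1 (a POU-domain transcription factor gene), Itgb1, Rc3h1, Eps15l1, 2310009B15Rik, 4930558K02Rik and Gm51582. Those near Triqk, Pou2f1 and Eps15l1 had a TetR peak within 1 kb. Leading regions of TetR included 4 on X, inside Arhgap6, Bclaf3, the kinase gene Rps6ka3 and the ubiquitin ligase gene Mid1. The other leading TetR regions were near Triqk, Nkain3, Gpr108 and Jam2, a junctional adhesion molecule gene whose end lay 0.188 kb from a TetR peak (chromosome 16, 84774196 to 84774428) seen in no library of the other lines. Those near Arhgap6, Triqk, Nkain3 and Gpr108 had a TetR-MYBTA peak within 1 kb.

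TetR was compared with WT to see what differed without MYBTA, whether from construct integration or from other differences between these lines. A peak was present in all 3 TetR and no WT libraries in 2629 regions and the reverse in 1597 regions. With lists of equal length the counts were 1758 and 1809. The leading TetR regions were near Ripk2, Rps6ka3, Jam2 and Slc39a10, and the leading WT regions near Ripk2, Slc39a10, Ttll5 and Galc. The region near Rps6ka3 lay in the same stretch of X from 150 to 170 Mb. The regions at Ripk2 and Slc39a10 were neighbouring positions listed in opposite directions, and all 4 leading WT regions had a TetR peak within 1 kb. TetR-MYBTA against WT gave 1437 and 3250 regions, with 2051 and 2082 at equal list length and 3625 and 3797 without TetR-MYBTA replicate 3.

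Peaks were redistributed between chromosomes in TetR-MYBTA. Chromosome 1 held 10.1 ± 0.0930% of its peaks (SD, n = 3) against 7.58 ± 0.0644% in the other 6 libraries, and chromosome 11 held 7.34 ± 0.192% against 5.72%. Chromosome 3 was also higher, at 6.36% against 6.02%. The share fell on 10 chromosomes, most on chromosome 19 (1.90 ± 0.0156% against 2.47%, a ratio of 0.769) and chromosome 9 (4.37 ± 0.0122% against 5.03%, a ratio of 0.868), then on 2, 5, 6, 7, 12, 15, 17 and 18. These 13 of 21 chromosomes passed after adjustment (exact permutation tests, adjusted p = 0.025 for chromosomes 1, 11, 19 and 9), with all 3 libraries beyond all other 6 on those 4. The other 6 libraries were not alike on all of them, as TetR and WT also differed. On chromosome 6 the shares in TetR-MYBTA, TetR and WT were 5.52%, 6.02% and 5.64%. On chromosome 7 they were 5.64%, 5.86% and 6.24%, and on chromosome 3 6.36%, 6.13% and 5.90%. Calls on chromosomes 3, 6 and 7 thus carry differences between TetR and WT and cannot be laid to TetR-MYBTA alone. A share is relative, so a rise on 1 chromosome lowers the rest, but that alone would lower them in proportion. The autosomes without a call had ratios from 0.964 (chromosome 4) to 1.03 (chromosome 14), though having no call itself keeps them near 1. For chromosomes 19 and 9 these values argue against the rise elsewhere as the only cause. The other chromosomes called as lower had ratios from 0.915 (chromosome 5) to 0.950 (chromosome 15), nearer that range. For them the rise elsewhere as the only cause stays open. On chromosome 19, 16.3% of regions with a peak in all 9 libraries moved up the TetR-MYBTA lists, the lowest share of any autosome or X. No chromosome passed when any TetR-MYBTA library was left out: with 2 against 6 libraries most calls stood at the smallest p possible (exact tests, adjusted p from 0.0625 to 0.0682), but chromosome 6 (0.2 to 0.214) and, without replicate 1 or 2, chromosome 7 (0.115) lay above it. Chromosomes 6 and 7 also lost their calls without any 1 of the other 6 libraries (exact tests, adjusted p from 0.0536 to 0.125), chromosome 3 without TetR replicate 1 or 2 (0.0577), chromosome 6 with lists of equal length (0.2) and in the upper 50% of each list (0.0893), and chromosome 15 in the latter (0.117). The differences kept their direction and much of their size. Chromosome 6 differed by -0.297 points at equal length and -0.363 in the upper 50% (-0.307 in the main setting), and chromosome 15 by -0.184 in the latter (-0.197). Leaving out 1 library gave -0.349 to -0.262 on chromosome 6, -0.475 to -0.368 on 7 (main -0.414) and 0.316 to 0.380 on 3 (main 0.344).

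Within chromosome 1 the rise lay in its distal part. From 88 Mb onward the share was 7.11 ± 0.0397% in TetR-MYBTA and 4.64 ± 0.0657% in the others, a ratio of 1.53, while the first 88 Mb gave a ratio of 1.03. On chromosome 11 the ratio was 1.55 in the first 44 Mb and 1.17 beyond. In TetR, X held 3.71 ± 0.0802% of peaks against 2.74% in WT (exact p = 0.1) and 2.80% in the other 6 libraries (exact p = 0.0119, adjusted p = 0.0714 over chromosomes, a comparison added after the data were seen). The TetR excess lay from 102 to 108 Mb, with a ratio of 2.11, and from 150 to 170 Mb, with a ratio of 2.15, whereas from 108 to 150 Mb the ratio was 1.01. A stretch of chromosome 6 from 68 to 84 Mb had a ratio of 1.79. The rule for boundaries was set after the data were seen. The stretches were chosen by these ratios, so no test of them is given.

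**Figure D2:**
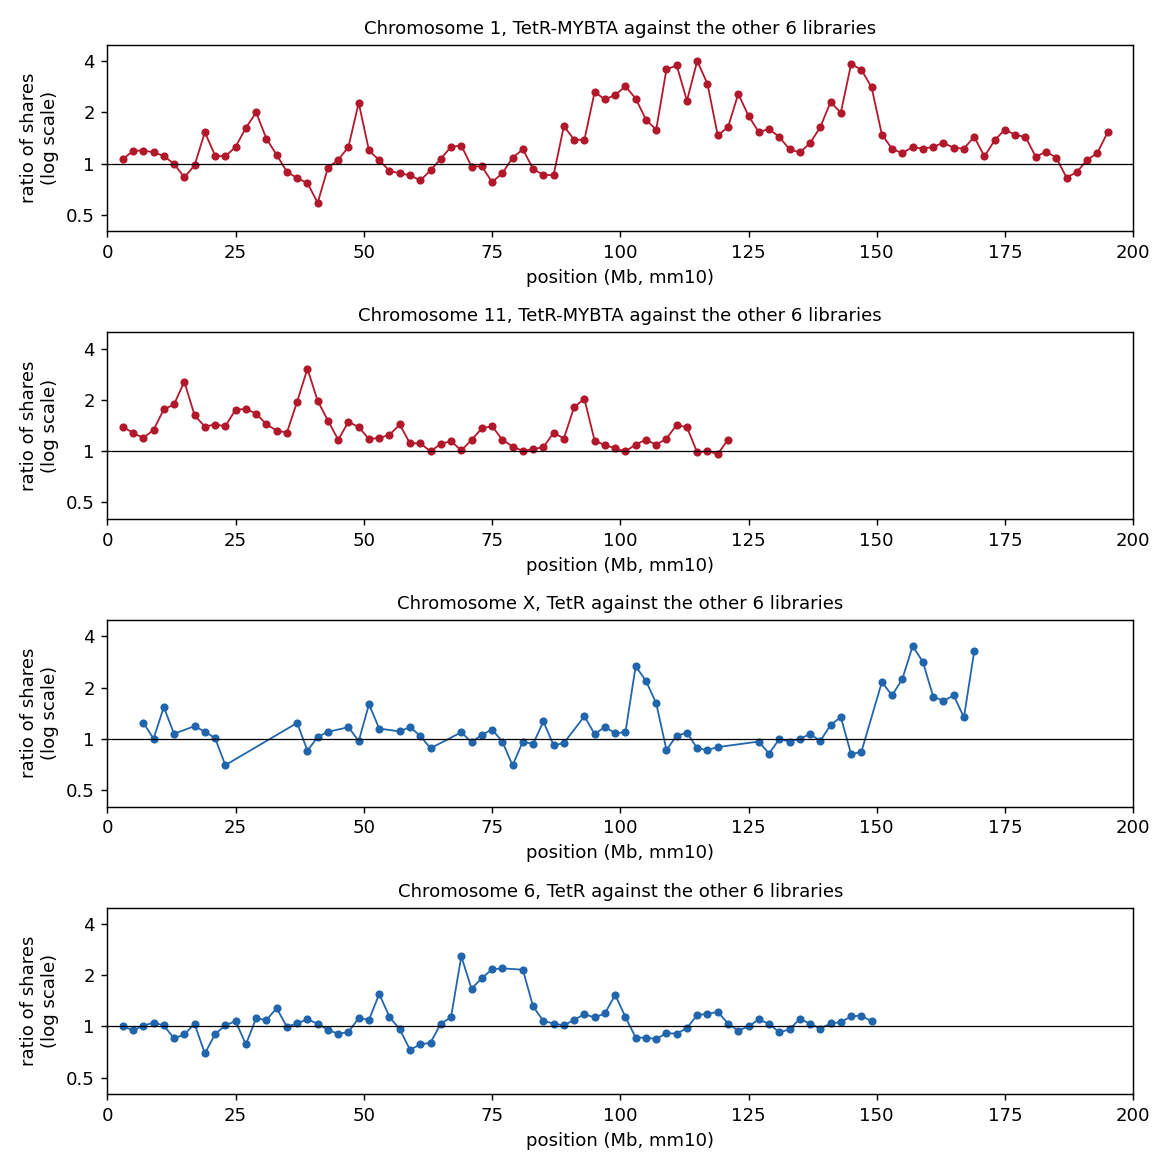
Ratio of the share of peaks in 2-Mb windows (log scale) along mm10 chromosomes 1 and 11 for TetR-MYBTA and X and 6 for TetR, each against the mean of the other 6 libraries. Windows with fewer than 90 peaks over the 9 libraries are left out; the raised stretches include chromosome 1 from 88 Mb and X from 150 to 170 Mb, with ratios of 1.53 and 2.15 over the whole stretch.

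A 1-Mb window of X (103000001 to 104000000) held 17 of the 1557 regions private to TetR, and the 1-Mb windows with most private regions of TetR-MYBTA (chromosome 1, 114000001 to 115000000, with no protein-coding gene) and of WT held 7 and 5. Ranked among all 84 choices of 3 libraries these numbers gave exact p = 0.0119, 0.0238 and 0.0357, but lines with more private regions in all reach higher numbers by that alone, and in 200-kb windows the TetR-MYBTA value did not pass (3 regions, exact p = 0.0595). As many regions were therefore drawn at random on each chromosome 10000 times, after the data were seen. Drawn from all regions, 0 draws reached the 17 of TetR (permutation p = 0.0001, the smallest they can give), and drawn from regions with a peak in exactly 3 libraries 36 did (p = 0.0037). The window lies in the stretch of X with a ratio of 2.11 in TetR, which the draws did not take into account. For TetR-MYBTA the permutation p was 0.056 and 0.0315, and for WT 0.104 and 0.124, and regions are not independent replicates. The TetR-MYBTA window likewise lies in the stretch of chromosome 1 from 88 Mb, with a ratio of 1.53. The draws spanned the whole chromosome, so they cannot tell a local cluster from that stretch. The TetR window held the X inactivation centre, including Xist, the RNA gene that silences X, its antisense Tsix, and Jpx, Ftx and Rlim. Xist lies within Tsix, with 1 private region inside both, and Jpx, Ftx and Rlim held 1, 1 and 2.

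Of 11 gene lists fixed before the data were examined, 6 held a lower share of TetR-MYBTA peaks within 50 kb of their genes than the other 6 libraries and 1 a higher share. The Hox clusters, the homeobox genes of body patterning, held 0.0321 ± 0.00266% of TetR-MYBTA peaks against 0.0680 ± 0.0102% (ratio 0.472, exact p = 0.0119, adjusted p = 0.0218), or 14 to 20 peaks per library against 30 to 53 in TetR and 38 to 46 in WT. Peaks numbered 2.67 ± 1.15 over Hoxd in TetR-MYBTA, 13 ± 4.58 in TetR and 12.7 ± 1.15 in WT (SD, n = 3 each), and 3.67, 11.3 and 10 over Hoxc. Over Hoxa they numbered 6, 13 and 10.7. Hoxb, on chromosome 11, had 5 in TetR-MYBTA, 4.67 in TetR and 9.67 in WT, and did not separate TetR-MYBTA from the other 6 (exact p = 0.357). The counts per cluster were made after the data were seen.

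The other lower lists differed less. Their ratios lay around that of the share of peaks inside protein-coding genes, 0.888 for TetR-MYBTA against the other 6 libraries. List windows also take in sequence between genes, so the measures differ. A loss specific to the genes of these lists is therefore not shown. Ratios were 0.836 for trophoblast genes, 0.869 for mesoderm and endoderm genes, 0.886 for housekeeping genes, 0.904 for formative and primed pluripotency genes (adjusted p = 0.0218 each, exact tests) and 0.907 for neural genes (adjusted p = 0.0374). The higher list was that of two-cell-like genes, with 15 to 18 peaks per TetR-MYBTA library against 11 to 14 (ratio 1.56, exact test, adjusted p = 0.0218); these are multicopy families, where read placement is uncertain. Naive pluripotency genes (ratio 0.982, exact p = 0.464), blood and MYB-associated genes (1.02, p = 0.298), MYB family and cofactor genes (1.01, p = 0.964) and feeder fibroblast genes (1.01, p = 0.774) did not separate. With lists of equal length the naive pluripotency genes did, with a share lower by a difference of -0.0288 percentage points in TetR-MYBTA (exact test, adjusted p = 0.0218), and the neural genes no longer did (adjusted p = 0.0655). The neural call also ended without TetR replicate 2 or 3 or any WT library (adjusted p from 0.0561 to 0.0842), and the mesoderm and endoderm call without TetR replicate 1 or 2 or WT replicate 1 or 2 (0.0561 to 0.0655). The differences themselves stayed similar, from -0.0152 to -0.0129 points for neural genes (-0.0142 with all libraries). For mesoderm and endoderm genes they ran from -0.0183 to -0.0169 (-0.0184). At equal list length the neural difference was -0.0181. No list passed when any TetR-MYBTA library was left out: without replicate 2 the difference for formative and primed pluripotency genes shrank from -0.0180 to -0.0103 percentage points (exact test, adjusted p = 0.246). All called lists kept their direction in these runs. The difference stayed from -0.0374 to -0.0349 for Hox clusters (-0.0359 with all libraries) and from -0.0300 to -0.0203 for housekeeping genes (-0.0245). No list passed within 10 kb, and without chromosomes 1, 11, 19 and X, a setting added after the data were seen, only 2 lists passed as lower, Hox clusters and housekeeping genes. There the difference was -0.0192 points for mesoderm and endoderm genes (-0.0184 with all chromosomes) and -0.0201 for trophoblast genes (-0.0223). It shrank to -0.0129 for formative and primed pluripotency genes (-0.0180) and to -0.00990 for neural genes (-0.0142). Against TetR alone no list could pass with 3 against 3 libraries.

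**Figure D3:**
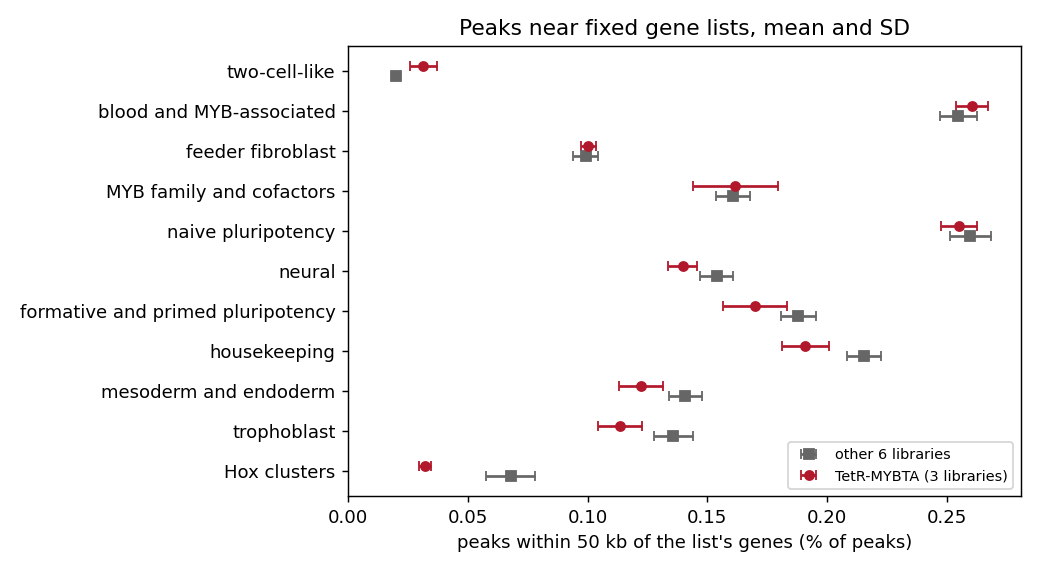
Percentage of peaks within 50 kb of the genes of each fixed list, mean and SD, for TetR-MYBTA (n = 3) and the other 6 libraries. The Hox clusters had the lowest ratio, 0.472, and the two-cell-like genes the highest, 1.56.

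At single list genes, Sox1, a neural transcription factor gene (chromosome 8, 12395519 to 12399555), and Hoxd13 (chromosome 2, 74668225 to 74671603) had a peak within 1 kb of a gene end in all 6 other libraries and in no TetR-MYBTA library. No list gene showed the reverse. Within 50 kb of Esrrb, a pluripotency factor gene, lay 12.3 ± 0.577 peaks in TetR-MYBTA (SD, n = 3) and 17.2 ± 1.47 in the other 6 libraries (exact p = 0.0119, not adjusted over the 6 genes tested). Around Myb itself there were 4.33 ± 1.15 against 6.67 ± 1.51 (exact p = 0.0714). Nanog had 8.67 against 10.3 (exact p = 0.226), Pou5f1 5.67 against 8.17 (exact p = 0.25), Sox2 3.67 against 5.33 (exact p = 0.131) and Klf4 4.67 against 5.50 (exact p = 0.417). These are counts of peaks, which move with list length.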

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

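The within-line similarity of peak sets, the lower share of peaks inside genes and the higher share between genes in TetR-MYBTA kept their direction in every alternative run. Leaving out 1 TetR-MYBTA library leaves 2 against 6, and no chromosome or list passed. Most stood at the smallest p that 2 against 6 allow, but others lay above it: without replicate 2, formative and primed pluripotency (exact tests, adjusted p = 0.246), mesoderm and endoderm and neural genes (0.131 each), without replicate 1 neural and without replicate 3 trophoblast genes (0.112 each), and chromosomes 6 and 7. The calls on chromosomes 3, 6 and 7 and on neural and mesoderm and endoderm genes also ended without some of the other libraries. Omitting the chromosomes 1, 11, 19 and X was chosen after seeing the data; the other settings given here were planned. The motif alternative was not run, and peak number has no value at equal list length. Where a value changed, the cause was not tested unless stated. Replicate numbers were not shown to pair the libraries. Deviations of same-numbered libraries correlated from -0.0826 to 0.173 (mean 0.0230), and those of differently numbered ones from -0.183 to 0.158 (mean -0.0111). Of 9 libraries 5 lay closest to their own number. No test of pairing was made, so weak pairing by number stays open. With the replicate block, where p cannot go below 0.25, peaks in TetR-MYBTA minus TetR differed by -11074 (exact sign-flip p = 0.25), so that fit could give no call and says nothing of stability. Presence or absence of a peak near the calling threshold limits the region counts.

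With lists of equal length, regions private to and missing in TetR-MYBTA numbered 1294 and 687, and those of TetR 955 and 540. TetR-MYBTA and TetR differed in 2834 and 2838 regions, TetR and WT in 1758 and 1809, and TetR-MYBTA and WT in 2051 and 2082; lists cut to 1 length draw such pairs together. Covered length in TetR-MYBTA minus TetR became 0.211 Mb, TetR minus WT -0.316 Mb and TetR-MYBTA minus the other 6 0.0526 Mb. Equal length itself removes the difference in peak number, so these values follow the peak width of each list. The share near gene ends became -1.95 points against TetR and -2.04 against the other 6. With the upper 50% of each list, 844 regions were missing in TetR-MYBTA, 3101 were in TetR and not TetR-MYBTA, 1732 and 1031 differed between TetR and WT, and 2062 were in WT and not TetR-MYBTA, as fewer peaks give fewer regions; the share near gene ends differed by -1.07 points from the other 6. With presence in at least 2 of 3, private and missing regions numbered 2647 and 4282 for TetR-MYBTA, 4900 and 1257 for TetR and 2555 and 1291 for WT, and pairs differed in 5066 and 12087 (TetR-MYBTA against TetR), 7835 and 4894 (TetR against WT) and 5086 and 8630 (TetR-MYBTA against WT). In 200-kb windows the most private TetR-MYBTA regions in one were 3 (exact p = 0.0595). Within 10 kb, 0 lists passed as higher and 0 as lower (exact tests; 5 at an unadjusted p under 0.05, lowest adjusted p = 0.0655). Without chromosomes 1, 11, 19 and X, 396 regions were private to TetR-MYBTA, 1025 distinguished it from TetR and 894 from WT, and 2 lists passed as lower.

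Naive pluripotency genes, with no call, passed as lower at equal list length (-0.0288 percentage points against the other 6, exact test, adjusted p = 0.0218), while neural genes lost their call there (-0.0181, adjusted p = 0.0655). Some list shares with no call changed sign, given here as TetR-MYBTA minus the group named, in percentage points of peaks. MYB family and cofactor genes gave -0.00960 against the other 6 and -0.00148 against TetR at equal list length, and -0.0277 and -0.00395 in the upper 50% of lists. Blood and MYB-associated genes gave -0.00517 against TetR at equal list length, -0.00399 against the other 6 and -0.00534 against TetR in the upper 50%, -0.00108 against TetR within 10 kb, and -0.0124 and -0.0132 without chromosomes 1, 11, 19 and X. Feeder fibroblast genes gave 0.000685 against TetR in the upper 50%, -0.00141 against the other 6 within 10 kb and -0.00441 without those chromosomes. Naive pluripotency genes gave 0.000317 against the other 6 and 0.00102 against TetR within 10 kb. Housekeeping genes, called lower within 50 kb, gave 0.000625 against the other 6 within 10 kb.

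Leaving out each library in turn, which eases the demand from 3 of 3 to 2 of 2, gave ranges of 749 to 1859 private and 1473 to 2327 missing regions for TetR-MYBTA, 1651 to 3215 and 339 to 556 for TetR, and 723 to 1486 and 229 to 460 for WT. TetR-MYBTA and TetR differed in 1627 to 3690 and 5144 to 8618 regions, TetR and WT in 2627 to 5205 and 1596 to 2994, and TetR-MYBTA and WT in 1436 to 3625 and 3242 to 5545. Private TetR-MYBTA regions numbered 1142 without its replicate 2 and 1859 without its replicate 3, and missing ones 2327 and 2159 without its replicates 1 and 2. From the other 6, covered length differed by -2.15 to -0.694 Mb, passing without TetR-MYBTA replicate 2 (exact p = 0.0357), peak width by -3 to 4.50 bp, and tags in peaks by -2.29 to -1.24 points, not passing without TetR-MYBTA replicate 3 (exact p = 0.143) or TetR replicate 3 (exact p = 0.0714). Peak width against WT differed by -6.50 to 1 bp. The share near gene ends differed by -0.210 to 1.60 points from TetR and -0.619 to 1.18 from the other 6. List shares ranged for MYB family and cofactor genes from -0.00559 to 0.0115 against TetR and -0.00908 to 0.00797 against the other 6, for feeder fibroblast genes from -0.00393 to 0.000113 and -0.000380 to 0.00288, and for naive pluripotency genes from -0.00555 to 0.00213 against TetR. Lists passing as higher ranged from 0 to 1 and as lower from 0 to 5, chromosomes from 0 to 4 and 0 to 8.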

Other observations

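All tests of explanations in this part were chosen after the results were seen.

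The share of peaks on chromosome 11 was 5.54 ± 0.00583% in TetR and 5.90 ± 0.0771% in WT (SD, n = 3 each, exact p = 0.1, the smallest that 3 against 3 can give). Every chromosome but 10 and Y gave that same p between TetR and WT. The difference of -0.367 points on chromosome 11 was exceeded on 4 (-0.399), 6 (0.386), 7 (-0.388) and X (0.968), so chromosome 11 did not stand out. Hoxb, on chromosome 11, had 9.67 ± 2.52 peaks in WT and 4.67 ± 1.53 in TetR (SD, n = 3 each, exact p = 0.1).

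The higher share of TetR-MYBTA peaks on chromosomes 1 and 11 may reflect extra copies of these chromosomes or parts of them, since gains of chromosomes occur in cultured embryonic stem cells. Of the regions with a peak in all 9 libraries, 75.3% on chromosome 1 and 88.2% on chromosome 11 moved up the TetR-MYBTA lists, against at most 49.5% on any other autosome or X. A general lean towards gene-poor sequence would raise windows of like gene number elsewhere, but windows of chromosomes 1 and 11 exceeded those by 1.34-fold, and the next chromosome by 1.07-fold. List length does not account for it either, as the ratio was 1.33 with lists of equal length. A broad regulatory change, DNA copies gained, and differences between clones picked during line making stay open, because no DNA copy measurement was used here.

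The TetR excess on X is consistent with an extra copy of parts of X, as 74.0% of common regions on X moved up the TetR lists against at most 59.0% elsewhere, and the ratio was 1.37 with lists of equal length. An extra copy of the whole chromosome is argued against by the 2-Mb windows: over all 66 windows of X with enough peaks the median ratio was 1.08, and 17 reached 1.3. From 108 to 150 Mb, a stretch set by where the raised ones ended, the ratio was 1.01 beside 2.15 further on, and before 102 Mb it was 1.07, slightly above every other library, which did not meet the stricter bound of no rise at all. Altered accessibility of these stretches without a copy change stays open.

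The excess of missing over private regions in TetR-MYBTA may come in part from its shortest list, replicate 3: without that library there were 0.874 missing regions per private one, against 1.98 with all peaks, whereas without replicate 1 or 2 missing regions still outnumbered private ones (2327 against 1015 and 2159 against 1142). They also did with presence in at least 2 of 3 libraries (4282 against 2647), so that list alone is not shown to account for the excess. The upper 50% of each list (844 against 569) keeps replicate 3 as the shortest list, so it cannot decide this. With lists of equal length there were 0.531, but that setting draws the counts together and private regions outnumbered missing ones in every line, so it does not decide whether list length in general is behind the excess. Sequencing depth is argued against, as total tags averaged 19.04 M in TetR-MYBTA, inside the range of the other 6 libraries, which began at 16.4 M. A lower share of tags in peaks, from the cells or from library quality, stays open.

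Among the 84 choices of 3 libraries, 2 gave as many private regions as TetR-MYBTA with 683 (highest other 1557, from TetR). Only 1 gave as many missing ones with 1349 (highest other 297). For TetR, 1 gave as many private ones with 1557 (highest other 683) and 2 as many missing ones with 297 (highest other 1349). For WT, 3 gave as many private ones with 665 (highest other 1557). These ranks gave exact p from 0.0119 to 0.0357, not adjusted over the counts. Such counts were thus rare among the choices, but the ranks cannot tell a construct from its line. For the 176 regions missing in WT, 7 choices gave as many (highest other 1349), so chance cannot be excluded. Between pairs of lines the 10 splits are too few for a share under 0.05: the real split was the 1 with the most regions each time, with 6784 for TetR-MYBTA against TetR (highest other 1046), 4226 for TetR against WT (979) and 4687 for TetR-MYBTA against WT (899).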
